A study of Mus musculus with 21 samples.

How the data were processed

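Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the binding of Foxa1, Foxa2, Foxa3 and Hnf4a in mouse cells of the C57BL/6 strain. The series holds 21 samples, of which 13 have a peak list and 8 are inputs whose own files were not analysed here. Mouse embryonic fibroblasts from embryos of 13.5 days post coitum were infected with retroviruses for Hnf4a and 1 of the 3 Foxa proteins, and cells were taken 48 hours later or as established hepatocyte-like (iHep) cells. The cells given a particular Foxa protein are called its line here, at both stages. A further sample carried a Foxa3 mutant named del2, fused to a Ty1 tag, and was precipitated with an antibody to the tag.

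The deposited files list each peak's chromosome, start, end and name and a score, and the sources used here do not state how the authors computed that score. The lowest deposited score in any list was 5.03. The score was used to rank or filter peaks within a list and, for the numbers of peaks alone, as 1 cut of 21.5 applied to all lists, although it is unknown whether scores are comparable between lists. The submitters' processing notes name BWA 0.6.2, MACS2 2.1.0, bedtools 2.16.2 and the genome build mm9, without a role for each. Each file belongs to 1 sample, and whether an input was used in the calling is not given in the sources used here. Positions are mm9 and are printed with the first base counted as 1. Against the mm9 chromosome lengths 8 peaks in 3 lists ended past a chromosome end, by 4 to 136 bp, while 346 peaks did so against mm10. No peak overlapped another peak of its own list.

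Samples were grouped by stage, line and antibody as their titles give them, with 1 library per group. The del2 sample's title and the series design place it at 48 hours, while its stage label says iHep, and it was grouped by its title. The titles also carry codes whose meaning is not given. The Foxa1 line has R222 at 48 hours and R225 in iHep cells, the Foxa2 and Foxa3 lines share R209 at 48 hours, the iHep Foxa2 line has R215 for Foxa2 and R242 for Hnf4a, and the iHep Foxa3 line has R170. Titles of the iHep Foxa3 line carry replicate number 3 and those of the other iHep lines 1. No read counts are in the files, so the depth of each library is unknown. With 1 library per group no replicate spread could be computed and no p-values are given.

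Lists were compared by overlap of at least 1 bp, as the share of the peaks of a list that overlap a peak of the other list. Each share carries a 95% Wilson interval. These intervals cover counting error only, and neighbouring peaks are not independent, so the true uncertainty is larger. The background was the mean over 200 random placements, in which the other list was shifted in a circle within each chromosome. It takes no account of which sequence is accessible or can be mapped, and most pairs of lists exceed every placement. Comparisons were made between the 3 Foxa lists of a stage, between the stages for each antibody and line, between Foxa and Hnf4a in each line and stage, between the 3 Hnf4a lists of a stage, and between iHep Hnf4a peaks absent from the 48-hour Hnf4a list and the 48-hour Foxa peaks of the line. Regions held by several lists were formed by merging overlapping peaks. The overlap code was tested on simulated data with 3000 peaks against 5000, where true shares of 0%, 10% and 50% were returned as 1.07%, 10.8% and 50.8% beside a random share of 1.06% to 1.08%.

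Alternatives fixed before the data were examined were an overlap of at least 50% of the shorter peak, peak centres within 200 bp, the upper 50% of each list by score, lists reduced to the length of the shortest, autosomes only, uniform random placement, a score above the highest median of the lists (21.5), peaks within 500 bp merged, and for del2 peak centres within 1 kb. The reduction to equal length was made within each set of lists compared, so the length can differ between comparisons. A pair of alternatives was added after the data were seen. The first removed 3 dense blocks of peaks, where each 48-hour Hnf4a list holds a chain of at least 5 peaks with gaps of up to 2 kb, with 10 kb on each side. The second joined peaks of a list up to 2 kb apart.

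The rule for named genes, fixed in advance, was to name gene list members and nearest genes only if an mm9 annotation was used, and otherwise to name regions alone: the 3 peaks with the highest score in each list, and the 5 regions with the best summed rank among those held by all 6 Foxa lists and among those held by all 6 Hnf4a lists. The gene table at hand is on GRCm38, so no gene was assigned to a position, and gene positions, gene lists and motifs were not analysed here. The text prints some of the top peaks. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.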

Results

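The binding of the 3 Foxa proteins and of Hnf4a was mapped in fibroblasts 48 hours after infection and in iHep cells. Foxa proteins are forkhead transcription factors and Hnf4a is a nuclear receptor, and both act in liver development. For each of the 3 lines and both stages there is 1 Foxa library and 1 Hnf4a library, and a single library of the tagged del2 mutant of Foxa3 stands beside them. The depth of the libraries is unknown, so the numbers of peaks cannot be corrected for it.

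At 48 hours the Foxa lists were of similar length, with 6781 peaks for Foxa1, 6827 for Foxa2 and 5690 for Foxa3. In iHep cells they ranged from 3435 peaks for Foxa1 to 10330 for Foxa2 and 12661 for Foxa3. Hnf4a had far fewer peaks than Foxa at 48 hours, with 418 in the Foxa1 line, 453 in the Foxa2 line and 370 in the Foxa3 line. The iHep Hnf4a lists held 1580, 2485 and 2506 peaks in the same order of lines. The 48-hour Hnf4a peaks were also narrow, with median widths of 87 bp, 89 bp and 93.5 bp against 205 to 361 bp in the iHep Hnf4a lists. The iHep Foxa3 list held 8245 peaks once those within 500 bp were merged, a smaller list than iHep Foxa2. Above a score of 21.5 the 48-hour Hnf4a lists held 2, 49 and 118 peaks and the iHep Hnf4a lists 117, 438 and 46 for the Foxa1, Foxa2 and Foxa3 lines, so above that score the Foxa3 line held fewer Hnf4a peaks in iHep cells. Whether scores are comparable between lists is unknown.

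**Figure D1:**
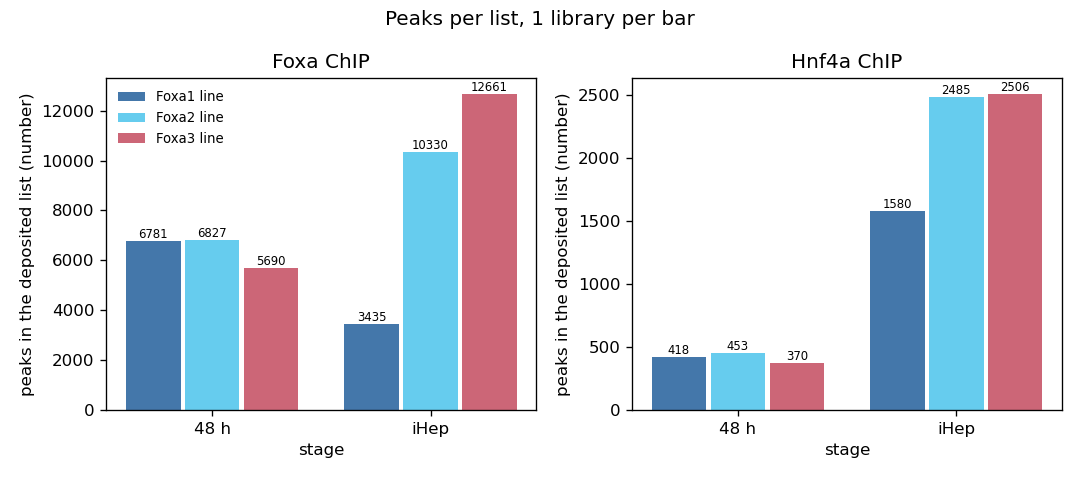
Number of peaks in each deposited list for the Foxa antibodies (left) and the Hnf4a antibody (right), by stage and line, with 1 library per bar and no error bar. The Hnf4a lists held 370 to 453 peaks at 48 hours and 1580 to 2506 in iHep cells.

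The next comparison asks whether the 3 Foxa proteins occupy the same sites at a stage. Foxa1 and Foxa2 shared many sites and Foxa3 shared few with either. At 48 hours 45.8% of Foxa1 peaks (interval 44.6% to 47.0%) overlapped a Foxa2 peak, while 1.83% of Foxa3 peaks (1.51% to 2.21%) overlapped a Foxa1 peak and 3.16% (2.74% to 3.65%) a Foxa2 peak. In iHep cells 85.3% of Foxa1 peaks (84.0% to 86.4%) overlapped a Foxa2 peak and 28.3% of the more numerous Foxa2 peaks (27.4% to 29.1%) a Foxa1 peak. There 1.72% of Foxa1 peaks (1.33% to 2.21%) and 2.19% of Foxa2 peaks (1.92% to 2.49%) overlapped a Foxa3 peak. The low shares of Foxa3 still exceeded all 200 random placements, whose highest values were 0.562% for Foxa3 at Foxa1 and at Foxa2 at 48 hours and 0.699% for iHep Foxa1 at Foxa3. Most pairs of lists did so, also those of unlike antibody, line and stage, so this says little about sites that Foxa3 shares with Foxa1 or Foxa2.

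Counted as merged regions, 5500 of the 15997 Foxa regions at 48 hours were held by Foxa3 alone, 3667 by Foxa1 alone, 3651 by Foxa2 alone, 3011 by Foxa1 and Foxa2 together and 77 by all 3. In iHep cells 12404 of 23238 regions were held by Foxa3 alone, 504 by Foxa1 alone, 7245 by Foxa2 alone, 2859 by Foxa1 and Foxa2 together and 61 by all 3. Across both stages, 940 regions were held by all 4 Foxa1 and Foxa2 lists, and 881 of these were in neither Foxa3 list. Both Foxa3 lists held 4134 regions, of which 4003 were in no Foxa1 or Foxa2 list.

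The sharing of Foxa1 and Foxa2 rose with peak score. At 48 hours 26.8% of the lowest scoring 25% of Foxa1 peaks overlapped a Foxa2 peak and 73.3% of the highest scoring 25% did. In iHep cells the same shares were 72.6% and 98.6%. Of the highest scoring 25% of 48-hour Foxa3 peaks, 2.67% (1.95% to 3.64%) overlapped a Foxa1 peak and 4.64% (3.66% to 5.86%) a Foxa2 peak. Some shares that involve Foxa3 also rose with score, at a low level. Between the lowest and highest scoring 25%, Foxa1 peaks at Foxa3 peaks rose from 0.236% to 3.83% at 48 hours. In iHep cells they rose from 0.698% to 3.03%, while iHep Foxa3 peaks at Foxa2 peaks stood at 2.31% in both groups. With peak centres required to lie within 200 bp, the Foxa3 shares at 48 hours were 1.07% at Foxa1 and 1.81% at Foxa2, and with lists of equal length 58.1% of iHep Foxa1 peaks lay at Foxa2 peaks. At equal length 0.408% of iHep Foxa1 peaks and 0.699% of iHep Foxa2 peaks lay at Foxa3 peaks. Each Foxa protein was mapped with its own antibody and in its own line, so a difference between the proteins and a difference between antibodies cannot be told apart.

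**Figure D2:**
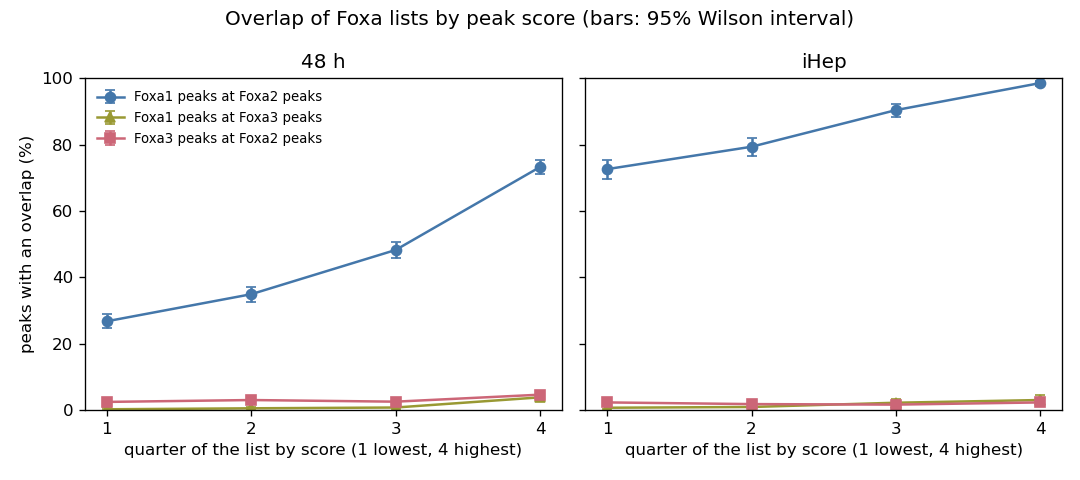
Share of peaks (%) with an overlap in another Foxa list of the same stage, for 4 equal groups of the list by score from lowest (1) to highest (4), with 95% Wilson intervals. Foxa1 peaks at Foxa2 peaks reached 73.3% at 48 hours and 98.6% in iHep cells in the highest scoring group. The shares that involve Foxa3 stayed at or below 4.64%, although Foxa1 peaks at Foxa3 peaks also rose with score, to 3.83% and 3.03%.

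The 12 peaks that are the top 3 of the Foxa1 and Foxa2 lists of both stages lay at 6 distinct loci, of which 4 overlapped a 48-hour Foxa3 peak and 0 an iHep Foxa3 peak. Of the top 3 peaks of the 48-hour Foxa3 list 1 overlapped a Foxa1 or Foxa2 peak, on chromosome 12 at 55838462 to 55839998. The highest scoring peak of the 48-hour Foxa1, 48-hour Foxa2 and iHep Foxa1 lists was the same locus on chromosome 10, at 86307872 to 86308791 in the 48-hour Foxa1 list with a score of 957, and it ranked next to highest in the iHep Foxa2 list. It also held a 48-hour Foxa3 peak and iHep Hnf4a peaks of the Foxa1 and Foxa2 lines. A locus on chromosome 4, at 3734049 to 3734915, gave the highest score of the iHep Foxa2 list (312) and held peaks in all 4 Foxa1 and Foxa2 lists and in neither Foxa3 list. The highest scoring 48-hour Foxa3 peak, on chromosome 11 at 87236025 to 87237459 with a score of 535, overlapped an iHep Foxa3 peak and no Foxa1 or Foxa2 peak. All 3 of the highest scoring iHep Foxa3 peaks, among them chromosome 11 at 115884470 to 115885880 with a score of 96.1, overlapped a 48-hour Foxa3 peak and no Foxa1 or Foxa2 peak.

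All 6 Foxa lists shared 12 regions. The 5 with the best summed rank lay on chromosome 1 at 173432130 to 173433966, chromosome 17 at 43012474 to 43014814, chromosome 8 at 96909764 to 96911968, chromosome 3 at 146162251 to 146163691 and chromosome 7 at 148661866 to 148663090. Their best rank in any list was 27, reached by the chromosome 1 region in the 48-hour Foxa3 list.

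The comparison of stages asks how much of the early binding was present in the established cells. Within lists of the same antibody and line, Foxa3 kept most of its peaks and the other proteins kept fewer. Of the 48-hour peaks, 30.8% for Foxa1 (29.7% to 31.9%), 31.5% for Foxa2 (30.4% to 32.6%) and 74.2% for Foxa3 (73.1% to 75.3%) overlapped an iHep peak of the same antibody and line. Random placement gave at most 0.236%, 0.645% and 0.826%. Seen from the iHep lists, 60.8% of Foxa1 peaks (59.2% to 62.4%), 20.8% of Foxa2 peaks (20.0% to 21.6%) and 43.8% of Foxa3 peaks (43.0% to 44.7%) were already peaks at 48 hours. With the lists of each pair cut to equal length the 48-hour shares were 44.1%, 25.4% and 54.4%, with Foxa3 still the highest. The lengths then still differed between the proteins, at 3435, 6827 and 5690 peaks. With peak centres within 200 bp the shares were 30.5%, 30.6% and 54.7%. Of the 48-hour Foxa1 peaks 52.8% (51.6% to 54.0%) overlapped an iHep Foxa2 peak, from a list longer than that of iHep Foxa1. A Foxa1 peak absent from the iHep Foxa1 list was thus not always without Foxa in iHep cells.

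Foxa peaks found at both stages had higher scores within their list than peaks found at 1 stage. In the 48-hour Foxa1 list the median score was 27.5 for the 2087 shared peaks and 15.8 for the 4694 others. In the 48-hour Foxa2 list the medians were 19.7 and 15.0, and in the 48-hour Foxa3 list 15.8 and 11.9. The share of 48-hour peaks kept in iHep cells rose from 12.4% to 57.6% between the lowest and highest scoring 25% of Foxa1 peaks, from 19.7% to 47.0% for Foxa2 and from 58.5% to 88.5% for Foxa3.

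The 48-hour Hnf4a lists shared 35.2% (30.7% to 39.9%), 53.9% (49.3% to 58.4%) and 11.1% (8.27% to 14.7%) of their peaks with the iHep Hnf4a list of the Foxa1, Foxa2 and Foxa3 line. These lists included 3 dense blocks that held 128, 125 and 119 of the 48-hour Hnf4a peaks in the same order, which is 30.6%, 27.6% and 32.2% of each list. The longest block lay on chromosome 9 at 3000016 to 3038294 and held 110, 106 and 106 of them. The others lay on chromosome 2 at 98502404 to 98507474 and on chromosome 10 at 7229418 to 7236934. Without the blocks 48.6%, 36.3% and 14.7% of the 48-hour Hnf4a peaks were kept. Removing the blocks thus raised the share in the Foxa1 and Foxa3 lines and lowered it in the Foxa2 line, and the Foxa1 line then had the highest. These shares also moved with other settings: they were 32.1%, 24.3% and 12.4% with peak centres within 200 bp, 31.1%, 39.4% and 1.08% in the upper 50% of the lists by score and 21.3%, 39.3% and 5.95% with lists of equal length. The Foxa3 line stayed the lowest, while the order of the other two changed. Unlike for Foxa, kept 48-hour Hnf4a peaks, blocks included, did not have clearly higher scores. The median scores of shared and other peaks were 7.94 and 7.80 in the Foxa1 line, 7.89 and 9.05 in the Foxa2 line and 9.74 and 19.3 in the Foxa3 line. Between the lowest and highest scoring 25% the share kept fell from 71.9% to 33.6% in the Foxa2 line and from 21.5% to 4.30% in the Foxa3 line, and was 30.5% and 34.3% in the Foxa1 line. In the Foxa2 line all 125 block peaks counted as kept, under iHep peaks of up to 29305 bp, and the trend without the blocks was not computed. Among iHep Hnf4a peaks, those found at both stages did score higher than the others. Their medians were 15.9 against 11.1 in the Foxa1 line, 22.0 against 12.7 in the Foxa2 line and 12.7 against 10.1 in the Foxa3 line.

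**Figure D3:**
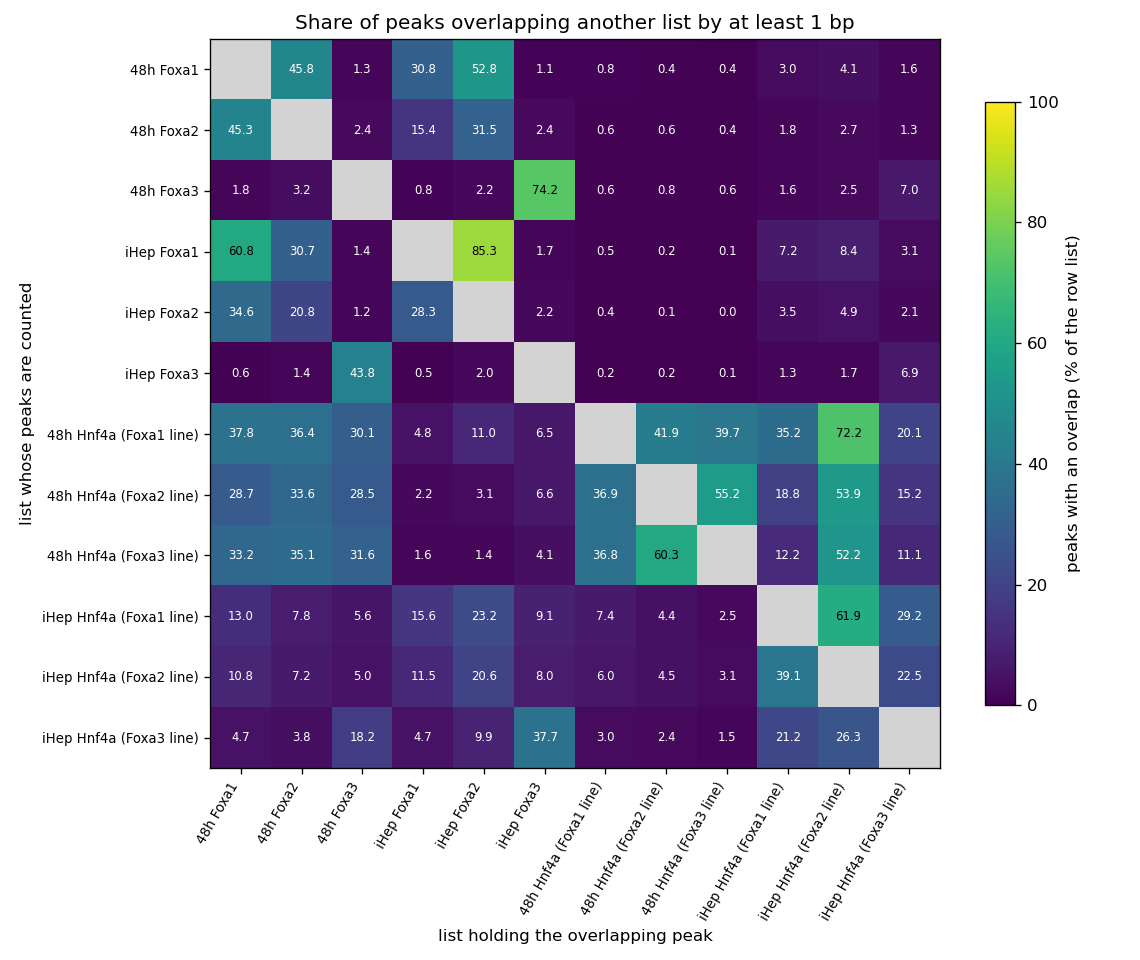
Share of the peaks of each row list (%) that overlap a peak of each column list by at least 1 bp, all peaks included, with 1 library per list. Foxa1 and Foxa2 lists share up to 85.3% of their peaks, the 48-hour Foxa3 list shares 74.2% with the iHep Foxa3 list, and the 48-hour Hnf4a lists share 36.8% to 60.3% with each other.

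The Foxa and Hnf4a lists of a line were compared to ask whether both factors were found at the same sites. At 48 hours 37.8% of Hnf4a peaks in the Foxa1 line (33.3% to 42.5%), 33.6% in the Foxa2 line (29.4% to 38.0%) and 31.6% in the Foxa3 line (27.1% to 36.5%) overlapped a Foxa peak of the line. Most of these lay in the dense blocks. Without the blocks the shares were 14.1% (10.6% to 18.6%), 11.6% (8.56% to 15.5%) and 3.19% (1.62% to 6.16%). In the Foxa1 and Foxa3 lines the share at the own Foxa protein was not clearly above that at Foxa2: without the blocks Hnf4a peaks of the Foxa3 line lay at Foxa1 peaks in 3.19% (8 of 251) and at Foxa2 peaks in 7.97% (20 of 251) of cases. Those of the Foxa1 line lay at Foxa2 peaks in 12.4% (36 of 290) and at Foxa3 peaks in 4.83% (14 of 290), and those of the Foxa2 line at Foxa1 peaks in 4.57% (15 of 328) and at Foxa3 peaks in 6.40% (21 of 328). With lists of equal length, blocks included, the own-line shares were 0.718%, 3.75% and 0%, and the Foxa1 and Foxa3 line values no longer exceeded every random placement.

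In iHep cells 15.6% of Hnf4a peaks in the Foxa1 line (13.9% to 17.5%), 20.6% in the Foxa2 line (19.0% to 22.2%) and 37.7% in the Foxa3 line (35.8% to 39.6%) overlapped an iHep Foxa peak of the line. Random placement gave at most 0.380%, 0.765% and 0.638%. The Foxa3 line stood apart in both directions. Its Hnf4a peaks overlapped iHep Foxa1 peaks in 4.75% (3.98% to 5.65%) and iHep Foxa2 peaks in 9.90% (8.79% to 11.1%) of cases, and the Hnf4a peaks of the Foxa1 and Foxa2 lines overlapped iHep Foxa3 peaks in 9.11% (7.79% to 10.6%) and 8.05% (7.04% to 9.18%). Hnf4a peaks of the Foxa1 line overlapped iHep Foxa2 peaks in 23.2% of cases (21.2% to 25.3%), more often than their own line's Foxa1 peaks, from a Foxa2 list of 10330 peaks against 3435. With the lists of each pair cut to equal length, at 1580, 2485 and 2506 peaks, the own-line shares were 7.97%, 8.25% and 15.5%. The Foxa3 line remained the highest. In the Foxa1 and Foxa3 lines both antibodies carry the same title code, and in the Foxa2 line they do not.

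**Figure D4:**
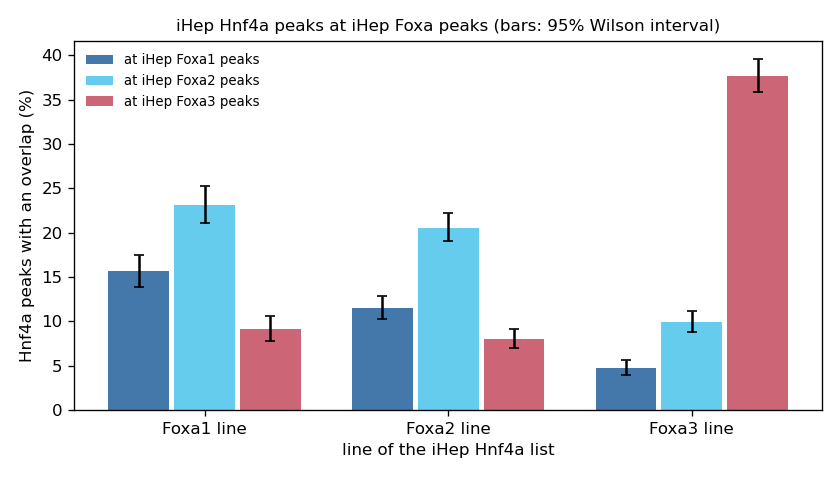
Share of iHep Hnf4a peaks (%) that overlap iHep Foxa1, Foxa2 and Foxa3 peaks, by the line of the Hnf4a list, with 95% Wilson intervals. In the Foxa3 line 37.7% lay at Foxa3 peaks, against 9.11% and 8.05% in the Foxa1 and Foxa2 lines.

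The Hnf4a lists of a stage were obtained with the same antibody target in 3 lines. In iHep cells the Foxa1 and Foxa2 lines shared the most, with 61.9% of Hnf4a peaks of the Foxa1 line (59.5% to 64.3%) at peaks of the Foxa2 line. The Foxa3 line held 29.2% (27.1% to 31.5%) of the Foxa1 line's and 22.5% (20.9% to 24.2%) of the Foxa2 line's Hnf4a peaks. As merged regions, 387 of 4813 were held in all 3 lines and 1728 in the Foxa3 line alone. Of those 387 regions, 27.4% (23.2% to 32.0%) overlapped an iHep Foxa2 peak, 19.1% (15.5% to 23.3%) an iHep Foxa1 peak and 17.6% (14.1% to 21.7%) an iHep Foxa3 peak.

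At 48 hours the Hnf4a lists of the Foxa2 and Foxa3 lines, which share the title code R209, had the most in common. Of the Foxa3 line's peaks 60.3% (55.2% to 65.1%) were in the Foxa2 line and 36.8% (32.0% to 41.8%) in the Foxa1 line. Without the dense blocks these shares were 49.8% (43.7% to 55.9%) and 16.3% (12.3% to 21.4%). Only 1 pair of lines shares a code, so code and line cannot be separated here.

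Among regions held by all 6 Hnf4a lists, 14 in number with 2 in dense blocks, the best summed rank belonged to chromosome 6 at 85087100 to 85087841. It was followed by chromosome 16 at 34861900 to 34862868, chromosome 6 at 120404538 to 120405178, chromosome 18 at 90771441 to 90772167 and chromosome 13 at 24287020 to 24287763. The chromosome 18 region runs 136 bp past the mm9 end of its chromosome at 90772031. The highest scoring Hnf4a peak of the iHep Foxa1 and Foxa2 lines was the same locus on chromosome 5, at 9040692 to 9041433 in the Foxa2 line with a score of 115, and it overlapped iHep Foxa1, iHep Foxa2 and 48-hour Foxa1 peaks.

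The last comparison of these lists asks whether sites that gained Hnf4a between the stages already held Foxa at 48 hours. Gained here means absent from the 48-hour Hnf4a list. A weak 48-hour library would also make iHep peaks appear gained, and this was not tested. In the 48-hour Hnf4a lists 78.9%, 73.7% and 66.5% of peaks were under 150 bp wide in the Foxa1, Foxa2 and Foxa3 lines. Of the iHep Hnf4a peaks absent from the 48-hour Hnf4a list, 178 of 1463 in the Foxa1 line (12.2%, 10.6% to 13.9%), 147 of 2374 in the Foxa2 line (6.19%, 5.29% to 7.23%) and 450 of 2469 in the Foxa3 line (18.2%, 16.8% to 19.8%) overlapped a 48-hour Foxa peak of the line. Random placement gave at most 0.615%, 0.548% and 0.648%. The overlap was not particular to the own Foxa protein in the Foxa2 line. Of all its iHep Hnf4a peaks, gained or not, 10.8% lay at 48-hour Foxa1 peaks and 7.16% at 48-hour Foxa2 peaks. In the Foxa1 and Foxa3 lines the own 48-hour Foxa list gave the highest share, at 13.0% and 18.2%. The Hnf4a peaks present at both stages overlapped 48-hour Foxa peaks in 23.9% (17.1% to 32.4%), 27.9% (20.4% to 36.9%) and 18.9% (9.48% to 34.2%) of cases, from 117, 111 and 37 peaks. The intervals of gained and kept peaks are apart in the Foxa1 and Foxa2 lines and overlap in the Foxa3 line. With the blocks removed the kept shares were 21.2% (14.7% to 29.7%), 25.0% (17.5% to 34.3%) and 18.2% (8.61% to 34.4%). With peak centres within 200 bp the gained shares were 10.6%, 5.78% and 9.33%, so the Foxa3 line was then no longer the highest. With lists of equal length the gained shares fell to 1.70%, 1.01% and 2.55%, from 352, 395 and 353 peaks.

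The tagged del2 mutant of Foxa3 was set beside intact Foxa3. Its list held 1 peak, on chromosome 17 at 35848708 to 35848794, 87 bp wide with a score of 7.14, against 5690 peaks in the 48-hour Foxa3 list. This peak overlapped peaks of the 48-hour Foxa1, iHep Foxa1, iHep Foxa2 and iHep Foxa3 lists and none of the 48-hour Foxa3 list. The mutant was precipitated through its tag and Foxa3 with an antibody to Foxa3, and an intact tagged Foxa3 was not analysed here, so the difference cannot be assigned to the mutation alone.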

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

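The tests in this part were chosen after the result was seen, except the merging of peaks within 500 bp, which was fixed before the data were examined, and for the Hnf4a peaks of the Foxa3 line the search in other lines and the count of clusters, which were chosen after the pattern but before their own results. The Foxa lists changed in opposite directions between the stages: from 48 hours to iHep cells the Foxa1 list changed by -3346 peaks, the Foxa2 list by 3503 and the Foxa3 list by 6971. With peaks within 500 bp merged the changes were -3301, 3455 and 3001, so the Foxa3 list no longer changed the most. This difference between lines was not tested, since each list comes from 1 library of unknown depth.

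Foxa3 peaks lay apart from Foxa1 and Foxa2 peaks at both stages. At 48 hours a difference in sequencing run does not account for it, if the title code stands for one. There Foxa3 and Foxa2 share a code and 3.16% of Foxa3 peaks lay at Foxa2 peaks, against 45.8% of Foxa1 peaks with another code. In iHep cells each Foxa list has its own code, so a difference in run is not excluded there. Weak peaks do not account for the separation at 48 hours. Of the highest scoring 25% of 48-hour Foxa3 peaks 2.67% lay at Foxa1 peaks, against 75.5% for that part of the Foxa2 list. The 4.92% of that part of the Foxa3 list (3.91% to 6.17%) with a Foxa1 or Foxa2 peak decides nothing on loci that every antibody enriches, which would raise the overlap, and other targets of the Foxa3 antibody cannot be told apart from Foxa3 binding, because the only tagged list is that of the del2 mutant, with 1 peak. Binding of the Foxa3 protein to sites of its own, the difference the design is built on, may also explain the pattern and was not tested apart from the antibody.

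The 3 dense blocks of the 48-hour Hnf4a lists were also weighed, and neither explanation was excluded. All 3 blocks held a peak in each 48-hour Foxa list, and all 3 chains of at least 5 peaks found in any 48-hour Hnf4a list held peaks in all 3 lines. Reads of high-copy repeats collected at few loci and Hnf4a binding recruited by the Foxa protein of each line may both give this, so they cannot be told apart here. In iHep cells the blocks differed between lists: the Hnf4a list of the Foxa2 line covered all 128, 125 and 119 of the 48-hour Hnf4a block peaks of the 3 lines, with peaks of up to 29305 bp, while those of the Foxa1 and Foxa3 lines covered 3 to 8, the iHep Foxa1 list 2 to 4 and the iHep Foxa2 and Foxa3 lists 0. Repeat content was not analysed here.

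In iHep cells Hnf4a peaks of the Foxa3 line lay at Foxa3 peaks more often than in other lines. Of these Hnf4a peaks 18.2% (16.8% to 19.8%) lay at 48-hour Foxa3 peaks, which have another title code, against 4.71% at 48-hour Foxa1 peaks. This does not exclude a shared run, because 43.8% of all iHep Foxa3 peaks lay at 48-hour Foxa3 peaks. Of the gained Hnf4a peaks at iHep Foxa3 peaks 44.3% did so too, so signal shared within the run could give the same overlap. Repeated counting of clustered peaks does not account for it, as counting clusters once left 40.0% (37.8% to 42.2%) against 9.43% in the Foxa1 line. Clusters placed alike in both lists would still overlap after joining, so clustering common to both lists is not excluded. Of 226 chains of at least 5 iHep Foxa3 peaks, 102 (45.1%) held an iHep Hnf4a peak of this line. Loci enriched by any antibody in this line remain a candidate explanation: of the 945 Hnf4a peaks at Foxa3 peaks 14.4% (12.3% to 16.8%) were Hnf4a peaks in another line, against 41.1% (38.7% to 43.6%) of the 1561 others. Hnf4a binding that depends on Foxa3 predicts the same and may equally explain it, so the result does not separate them. In the Foxa1 line the same shares were 70.0% and 67.3%, and in the Foxa2 line 57.5% and 43.6%.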

How the results depend on the processing

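The dense blocks and the joining of neighbouring peaks were chosen after the data were seen, and the other alternatives before. The ratio to random placement stayed above every placement for all 27 overlaps with autosomes only, with uniform placement, with an overlap of at least 50% of the shorter peak, with centres within 200 bp and with joined peaks. With equal list lengths 2 ratios did not: the 48-hour Hnf4a peaks at Foxa peaks of the Foxa1 line, at 46.2 times the random mean from 3 of 418 peaks, and those of the Foxa3 line, which turned to 0 from 0 of 370 peaks. That setting keeps as few Foxa peaks as there are Hnf4a peaks. For 3 further ratios (2 in the upper 50% by score, 1 without the blocks) no random placement gave an overlap, so they have no value. All 27 shares stayed within their intervals with autosomes only. The shares outside their intervals follow, and apart from the smaller lists under equal lengths and the upper 50%, the cause was not tested. With an overlap of at least 50% of the shorter peak, iHep Foxa overlap was 1.16% (Foxa1 at Foxa3) and 1.60% (Foxa2 at Foxa3). 48-hour Foxa peaks kept were 71.3% (Foxa3). 48-hour Hnf4a peaks kept were 8.11% (Foxa3 line). The iHep Hnf4a at own Foxa was 35.8% (Foxa3 line). The iHep Hnf4a overlap was 21.4% (Foxa1 line at Foxa3 line) and 17.2% (Foxa2 line at Foxa3 line). Gained Hnf4a at 48-hour Foxa was 15.6% (Foxa3 line). With centres within 200 bp, 48-hour Foxa overlap was 44.6% (Foxa1 at Foxa2), 1.07% (Foxa3 at Foxa1) and 1.81% (Foxa3 at Foxa2). The iHep Foxa overlap was 83.9% (Foxa1 at Foxa2), 0.902% (Foxa1 at Foxa3) and 1.15% (Foxa2 at Foxa3). 48-hour Foxa peaks kept were 54.7% (Foxa3). 48-hour Hnf4a peaks kept were 24.3% (Foxa2 line). 48-hour Hnf4a at own Foxa was 10.8% (Foxa1 line), 9.27% (Foxa2 line) and 10% (Foxa3 line). The iHep Hnf4a at own Foxa was 13.7% (Foxa1 line), 18.7% (Foxa2 line) and 25.5% (Foxa3 line). 48-hour Hnf4a overlap was 65.9% (Foxa3 line at Foxa2 line). The iHep Hnf4a overlap was 59.1% (Foxa1 line at Foxa2 line), 22.2% (Foxa1 line at Foxa3 line) and 15.1% (Foxa2 line at Foxa3 line). Gained Hnf4a at 48-hour Foxa was 10.6% (Foxa1 line) and 9.33% (Foxa3 line). In the upper 50% by score, 48-hour Foxa overlap was 2.39% (Foxa3 at Foxa2). The iHep Foxa overlap was 0.932% (Foxa1 at Foxa3) and 1.14% (Foxa2 at Foxa3). 48-hour Foxa peaks kept were 29.2% (Foxa2) and 72.6% (Foxa3). 48-hour Hnf4a peaks kept were 39.4% (Foxa2 line) and 1.08% (Foxa3 line). 48-hour Hnf4a at own Foxa was 30.6% (Foxa1 line), 22.6% (Foxa2 line) and 42.7% (Foxa3 line). The iHep Hnf4a at own Foxa was 11.8% (Foxa1 line), 17.1% (Foxa2 line) and 27.5% (Foxa3 line). 48-hour Hnf4a overlap was 28.2% (Foxa1 line at Foxa2 line) and 28.6% (Foxa3 line at Foxa1 line). Gained Hnf4a at 48-hour Foxa was 9.54% (Foxa1 line), 4.42% (Foxa2 line) and 12.4% (Foxa3 line). With equal list lengths, iHep Foxa overlap was 58.1% (Foxa1 at Foxa2), 0.408% (Foxa1 at Foxa3) and 0.699% (Foxa2 at Foxa3). 48-hour Foxa peaks kept were 44.1% (Foxa1), 25.4% (Foxa2) and 54.4% (Foxa3). 48-hour Hnf4a peaks kept were 21.3% (Foxa1 line), 39.3% (Foxa2 line) and 5.95% (Foxa3 line). 48-hour Hnf4a at own Foxa was 0.718% (Foxa1 line), 3.75% (Foxa2 line) and 0% (Foxa3 line). The iHep Hnf4a at own Foxa was 7.97% (Foxa1 line), 8.25% (Foxa2 line) and 15.5% (Foxa3 line). 48-hour Hnf4a overlap was 31.6% (Foxa1 line at Foxa2 line) and 50.5% (Foxa3 line at Foxa2 line). The iHep Hnf4a overlap was 52.2% (Foxa1 line at Foxa2 line) and 23.0% (Foxa1 line at Foxa3 line). Gained Hnf4a at 48-hour Foxa was 1.70% (Foxa1 line), 1.01% (Foxa2 line) and 2.55% (Foxa3 line). Without the dense blocks, 48-hour Foxa overlap was 1.38% (Foxa3 at Foxa1) and 2.72% (Foxa3 at Foxa2). 48-hour Hnf4a peaks kept were 48.6% (Foxa1 line), 36.3% (Foxa2 line) and 14.7% (Foxa3 line). 48-hour Hnf4a at own Foxa was 14.1% (Foxa1 line), 11.6% (Foxa2 line) and 3.19% (Foxa3 line). 48-hour Hnf4a overlap was 19.0% (Foxa1 line at Foxa2 line), 16.3% (Foxa3 line at Foxa1 line) and 49.8% (Foxa3 line at Foxa2 line). With neighbouring peaks joined, 48-hour Foxa peaks kept were 77.6% (Foxa3). 48-hour Hnf4a peaks kept were 48.3% (Foxa1 line), 36.6% (Foxa2 line) and 15.4% (Foxa3 line). 48-hour Hnf4a at own Foxa was 16.1% (Foxa1 line), 11.2% (Foxa2 line) and 4.52% (Foxa3 line). The iHep Hnf4a at own Foxa was 40.0% (Foxa3 line). 48-hour Hnf4a overlap was 22.3% (Foxa1 line at Foxa2 line), 19.9% (Foxa3 line at Foxa1 line) and 51.1% (Foxa3 line at Foxa2 line). Gained Hnf4a at 48-hour Foxa was 20.6% (Foxa3 line). Of the numbers of peaks, those above a score of 21.5 were 2697, 2124 and 1360 for 48-hour Foxa1, Foxa2 and Foxa3, 1716, 4798 and 3019 for the iHep lists, 2, 49 and 118 for 48-hour Hnf4a, 117, 438 and 46 for iHep Hnf4a and 0 for del2. Merging within 500 bp left 252, 287 and 232 48-hour Hnf4a peaks and 8245 iHep Foxa3 peaks. Joining within 2 kb left 57.9%, 60.9% and 59.7% as many 48-hour Hnf4a peaks and 58.2% as many iHep Foxa3 peaks. No paired analysis was possible because no 2 groups share 2 replicate numbers, and leaving out a replicate is not possible with 1 library per group. Read depth is unknown, so its effect on any list length is unknown. Gene positions, gene lists and motifs and their alternatives were not run.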

Other observations

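The counts in this part were chosen after the data were seen, apart from the share of iHep Foxa2 peaks at 48-hour Foxa2 peaks. Foxa3 peaks lay in clusters in iHep cells. Of the iHep Foxa3 peaks 66.1% had another peak of the list within 2 kb, against 20.2% at 48 hours, 3.44% to 8.68% in the Foxa1 and Foxa2 lists and at most 3.20% under uniform placement of the iHep Foxa3 list. Chains of at least 5 iHep Foxa3 peaks numbered 226, and 172 of them (76.1%) held a 48-hour Foxa3 peak while 44 (19.5%) held a Foxa1 or Foxa2 peak of either stage. The longest lay on chromosome 19 at 5812430 to 5850576, with 42 iHep and 12 48-hour Foxa3 peaks over 38.1 kb. A pair of neighbouring chains on chromosome 6, at 52172259 to 52190469 and 52193492 to 52210124, held 15 and 18 iHep Foxa3 peaks and 18 and 10 iHep Hnf4a peaks of the Foxa3 line. In that line 40.4% of iHep Hnf4a peaks had a neighbour within 2 kb, against 4.87% and 8.69% in the Foxa1 and Foxa2 lines. Both clustered iHep lists carry the title code R170 and have narrow peaks, with median widths of 248 bp for Foxa3 and 205 bp for Hnf4a. The medians were 412 bp and 461 bp for iHep Foxa1 and Foxa2, 538 bp for 48-hour Foxa3, and 308.5 bp and 361 bp for the other iHep Hnf4a lists. Whether clusters reflect binding or how peaks were called in these libraries was not tested.

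Foxa3 peaks were also spread differently over chromosomes. Chromosome 11 held 8.77% of 48-hour Foxa3 peaks (8.06% to 9.53%) and 8.97% of iHep Foxa3 peaks (8.49% to 9.48%). The Foxa1 and Foxa2 lists held 4.10% to 5.24% on this chromosome, which makes up 4.59% of the assembled genome. The iHep Hnf4a lists of the Foxa1, Foxa2 and Foxa3 lines held 6.46%, 5.59% and 7.98% there, so the excess was not limited to the Foxa3 antibody. Chromosome 17, 3.59% of the genome, held 5.57% and 5.93% of the Foxa3 lists, against 2.65% to 3.24% of the Foxa1 and Foxa2 lists. Chromosome X, 6.28% of the assembled genome, held at most 3.51% of the peaks of any list. It held 6 iHep Hnf4a peaks of the Foxa3 line, or 0.239% (0.110% to 0.521%). The shares were 1.27% (0.821% to 1.95%) in the Foxa1 line and 2.21% (1.70% to 2.87%) in the Foxa2 line. The iHep Foxa3 list held 1.45% (1.25% to 1.67%) there, against 1.80% (1.41% to 2.31%) for iHep Foxa1 and 2.29% for iHep Foxa2. Of the 10330 iHep Foxa2 peaks, 34.6% (33.7% to 35.6%) overlapped a 48-hour Foxa1 peak and 20.8% (20.0% to 21.6%) a 48-hour Foxa2 peak, with 1644 at both, 1933 at Foxa1 alone, 504 at Foxa2 alone and 6249 at neither.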
